A study of Mus musculus with 8 samples.

How the data were processed

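RNA was isolated from the progeny of 10000 cultured mouse HSPCs per sample, and libraries were prepared from 350 ng of total RNA with a stranded total RNA kit, per the labels' protocols. Cultures ran for 7 days with stem cell factor at 100 ng/ml and Flt3 ligand at 2 ng/ml, with part of the medium exchanged after 3 or 4 days, and malonyl-CoA was present at 100 µM in 1 of the 2 groups. The 4 control and 4 malonyl-CoA libraries were assigned from the sample titles. The design text calls them biological replicates, but does not say whether a replicate stands for an animal, a pool of animals or a culture. P-values of the gene tests and of the permutation tests therefore measure the spread between these samples.

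The deposited files hold raw counts per Ensembl gene, 1 library per file, with no normalization by the authors visible in the values, which are whole numbers with a different total in each library. Reads were processed with cutadapt 1.8, STAR 2.5.2b and HTSeq 0.6.1 on genome build GRCm38, per the submitters' processing notes. The annotation release and the strand setting of the counter are not given in the sources used here. Where a gene overlaps another or has an antisense partner, its count is therefore uncertain. Each file also ends with counter classes that name no gene, and these were kept out of library sizes and tests. Reads in no gene made up 1.11% to 2.94% of tallied reads, ambiguous reads 0.715% to 0.891% and reads with several positions 38.2% to 51.1%. Genes with near-identical copies, such as ribosomal protein genes, lose reads to the last class. Of 48709 gene identifiers, 48349 matched GENCODE M21 (also GRCm38), from which symbols, coordinates and transcript sequences were taken, and the rest held at most 0.0154% of a library's counts.

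Counts assigned to genes were 18233714, 18887518, 20820218 and 22079844 in controls 1, 3, 4 and 5, and 20298885, 19929316, 21308153 and 17492085 in malonyl-CoA 1, 3, 4 and 5. Genes near 1 CPM therefore rest on few reads and carry a large counting error.

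The main comparison used edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr (minimum count 10, minimum total 15), TMM factors, glmQLFit with robust estimation and the two-sided glmQLFTest, with no covariate. Benjamini-Hochberg adjustment ran over the 12696 genes kept, with a threshold of 0.05 and no minimum fold change. Log2 fold changes are malonyl-CoA minus control, and standard errors were taken as the absolute log2 fold change over the square root of the F statistic. Group levels are CPM with TMM factors. Log2 CPM used a prior count of 2.

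The 37 gene lists were written before the data were examined, from general knowledge: metabolic pathways around malonyl-CoA, stress and cell cycle programmes, and markers of blood and stromal cell types. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists, and each list needed at least 5 tested members. That preset takes members as nearly independent, so camera's p does not measure the spread of a list between libraries. Beside camera stand the number of members past the gene test over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives. A list score per library is the mean log2 CPM deviation of its members, compared by an exact permutation test of all 70 splits. That score test, corrections for GC content and for GC content and length (a loess fit per library with span 0.5 on genes with a mean log2 CPM above 2), and the comparison without control 5 and malonyl-CoA 4 were chosen after seeing the data. GC values were found for 99.9% of tested genes.

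Genes were named by a rule fixed before the data were examined. It takes up to 12 called genes per direction with a mean log2 CPM of at least 1 and no overlap between the groups, by fold change, or, where none is called, the 5 with the smallest unadjusted p. Predicted gene models were left out. It adds Acaca, Fasn, Mlycd and Cpt1a, and up to 4 members of each list with the smallest p in the list's direction, or in either where it has none. Not every gene that the rule names is described in the text. The share of counts in mitochondrial-encoded, ribosomal protein and the 10 most abundant genes was compared by exact permutation tests adjusted over 4 measures.

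The alternatives chosen before the data were examined were edgeR's RLE factors, library size only, no low-count filter, a filter of at least 1 CPM in 4 libraries, the replicate number as a block, each library and each pair of same-numbered libraries left out, DESeq2 1.42.0, limma-voom, the legacy edgeR fit, stricter thresholds and the removal of abundant gene classes. All were run. DESeq2 gave no adjusted p for 7912 genes, which were not counted as lost.

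The gene tests, the GC corrections and camera were tested on simulated data first: counts for the 12696 genes of the comparison of malonyl-CoA against control, drawn from the real means, library sizes and dispersions, with 200 genes changed. The changed genes and the list members were drawn from genes with a mean log2 CPM above 2. EdgeR recovered 73% of the 100 genes changed by 1 on the log2 scale and 97% of the 100 changed by 2, and called 12 unchanged genes, DESeq2 recovered 88% and 99% and called 39 unchanged genes, limma-voom 67% and 99% with 7, and edgeR with the block 62% and 99% with 8. A GC trend put into the simulated counts gave a rho of 0.692 between log2 fold change and GC share, and 0.0185 after the GC correction. Camera gave a list of 30 genes shifted by 0.5 an adjusted p of 2.32e-16 and called 0 of 36 unshifted lists. The simulated genes vary independently of each other, while in the real libraries the estimated correlation within a list was up to 0.88. The simulation therefore cannot measure how often camera calls unshifted lists in these data. Nor do its recovery rates give the share of changed genes that the gene tests would find in the real libraries.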

Results

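Gene expression was measured in mouse hematopoietic stem and progenitor cells (HSPCs), the bone marrow fraction without lineage markers that carries Sca1 and cKit and from which all blood lineages arise. Cells of C57Bl/6J mice were kept for 7 days in serum-free medium with stem cell factor and Flt3 ligand, either with 100 µM malonyl-CoA or without it. Malonyl-CoA is the substrate for chain extension in fatty acid synthesis and an inhibitor of carnitine palmitoyltransferase 1, which brings fatty acids into mitochondria for oxidation. Each of the 2 groups held 4 libraries, numbered 1, 3, 4 and 5 in both. The libraries were made from the progeny of 10000 seeded cells, so they describe cultures after 7 days and not the cells as sorted. Counts assigned to genes ranged from 17492085 in malonyl-CoA 5 to 22079844 in control 5. No pair of libraries agreed within sampling noise (lowest chi-square per gene 7.63 over the 28 pairs), and all 8 were kept as separate samples.

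Library composition varied within the groups, and none of the tested shares differed between them at an adjusted p under 0.05 in exact permutation tests. Mitochondrial-encoded genes took 4.09% ± 1.90 of gene counts in control and 2.45% ± 1.18 with malonyl-CoA (SD, n = 4 each, two-sided exact permutation p = 0.2, adjusted p = 0.267). Ribosomal protein genes took 6.54% ± 0.77 and 5.51% ± 1.16 (SD, n = 4 each, exact permutation p = 0.2, adjusted p = 0.267), and the 10 most abundant genes 7.81% ± 0.98 and 6.06% ± 1.12 (SD, n = 4 each, exact permutation p = 0.0857, adjusted p = 0.267). The smallest p that this test can give with 4 against 4 libraries is 0.0286. Adjusted over 4 measures, a single measure at that p could not pass, so these tests could hardly find a difference. The leading transcripts were mt-Co1, Eef1a1 and Mpo, the last encoding the myeloperoxidase of neutrophil granules, at 0.930% of gene counts on average. A pair of libraries stood apart. Malonyl-CoA 4 lay at 63.3 on the first principal component, which held 48.9% of the variance, with control 4 next at 25.3. In malonyl-CoA 4, 2.94% of tallied reads fell in no gene, against 1.11% to 1.56% in the controls. In control 5, log2 CPM deviations followed the GC share of transcripts with a Spearman's rho of -0.67 across genes, against 0.44 in malonyl-CoA 1. Genes are not independent replicates, so these values describe each library only.

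**Figure D1:**
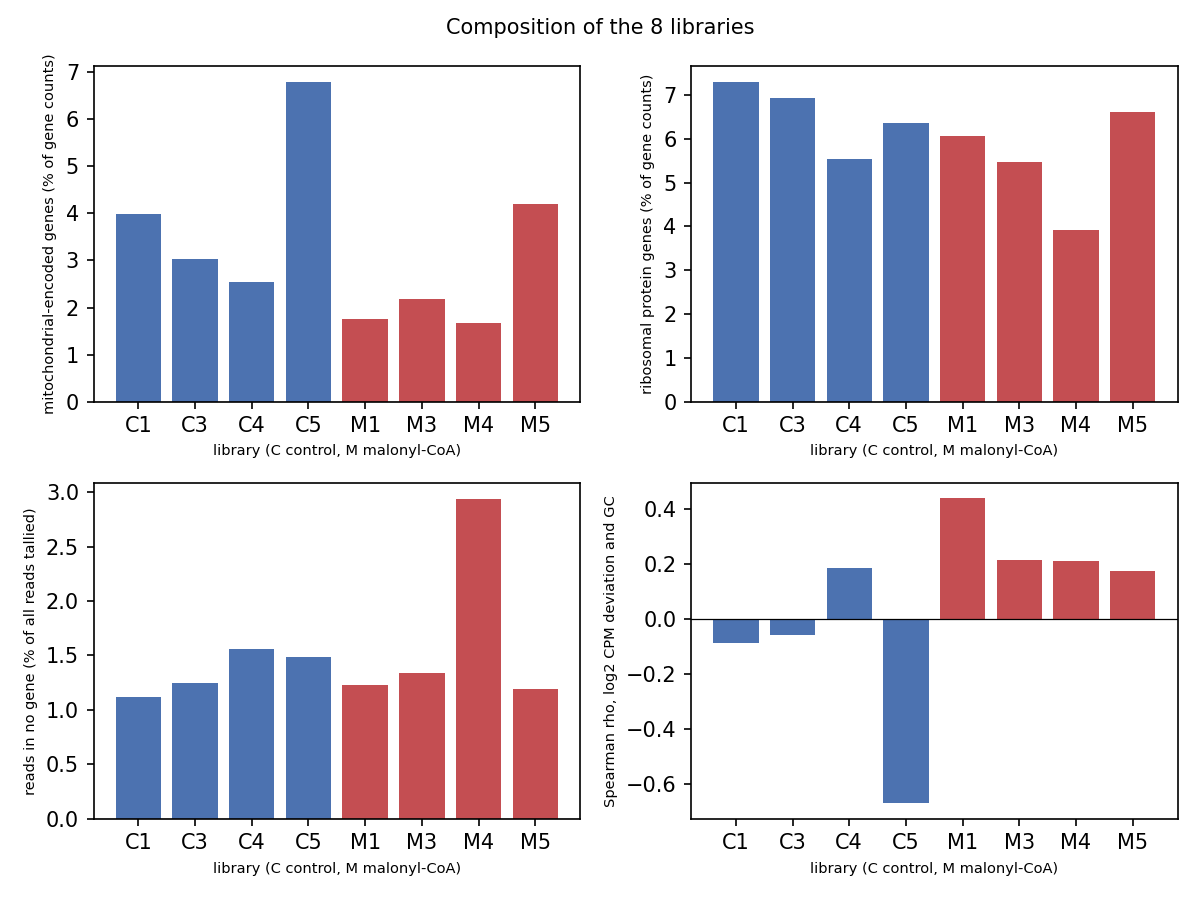
Bars give, for each of the 8 libraries, the percentage of gene counts in mitochondrial-encoded and in ribosomal protein genes, the percentage of tallied reads in no gene, and Spearman's rho across genes between log2 CPM deviation and GC share, with controls in blue and malonyl-CoA libraries in red. Malonyl-CoA 4 has the highest share of reads in no gene (2.94%), and control 5 the lowest rho (-0.67) and the highest mitochondrial share (6.79%).

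The first question was which genes differed between cultures with and without malonyl-CoA, and no gene passed the threshold in the main fit, which left the replicate numbers out. The genes with the smallest p were higher with malonyl-CoA, though none is called here. Marco, a scavenger receptor of macrophages (ENSMUSG00000026390, GRCm38 chromosome 1, 120474538 to 120505024), averaged 2.13 ± 0.53 CPM in control and 7.99 ± 1.54 with malonyl-CoA (SD, n = 4 each). Its log2 fold change was 1.89 (SE 0.23, edgeR adjusted p = 0.146), the smallest adjusted p of all genes. Mmp14, a membrane-bound matrix metalloproteinase (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364), stood at 4.62 ± 1.93 and 18.9 ± 2.92 CPM, a log2 difference of 2.03. Ly6i (ENSMUSG00000022586, chromosome 15, 74979534 to 74983430, log2 fold change 1.64), Bcl3, a nuclear regulator of NF-kB (1.34), and Gbp5, an interferon-inducible GTPase (1.06), followed, with an edgeR adjusted p of 0.218 each. On the lower side were Bpifc (ENSMUSG00000050108, chromosome 10, 85959340 to 86011895, log2 fold change -1.06), Tspan2 (-0.59), the apelin receptor gene Aplnr (-0.95), the lectin receptor gene Clec4a2 (-0.79) and Aldh6a1 (-0.63), a mitochondrial dehydrogenase that makes coenzyme A esters from malonate semialdehydes. Their edgeR adjusted p was 0.352 each. In all 10 of these genes the 4 malonyl-CoA libraries lay on one side of the 4 controls, which picking them by p from the same values favours.

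**Figure D2:**
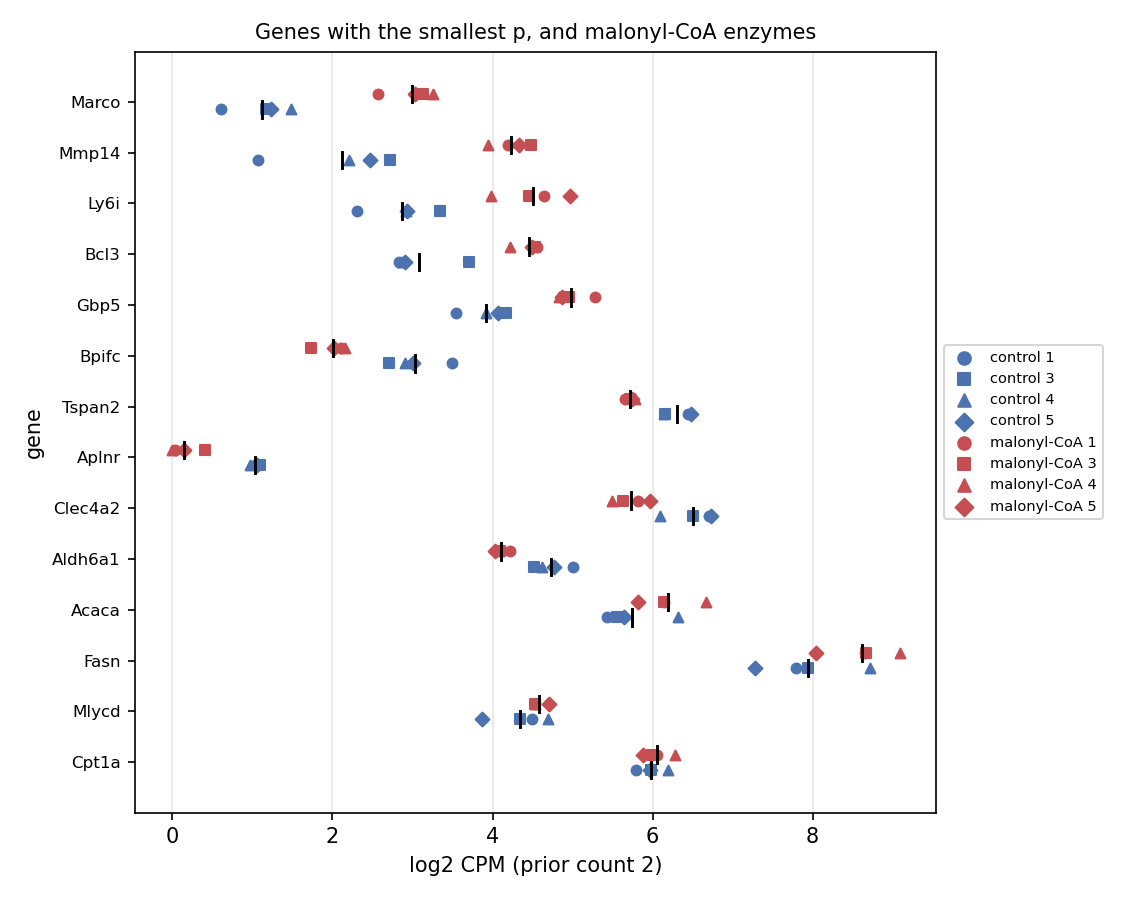
Points give log2 CPM (prior count 2) of each library for the 5 genes with the smallest p in each direction and for 4 malonyl-CoA enzymes, with controls in blue, malonyl-CoA libraries in red, symbols for the replicate number and black bars for the group means. The groups do not overlap in the first 10 genes and overlap in Acaca, Fasn, Mlycd and Cpt1a.

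Of 12696 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05, 690 were higher and 520 lower, 1210 in all where 635 would be expected with no difference. The 4 malonyl-CoA libraries lay above all controls in 408 genes and below them in 372, together 6.14% of genes, where chance gives 2.86% on average. Genes move together, so a single grouping can lie far from either expected value by chance. Of 35 splits of the libraries, 8 gave at least 1210 genes at an unadjusted p under 0.05, the real grouping included. The share of genes without overlap was not compared over the splits. With the replicate number as a block edgeR called 172 genes, with a smallest adjusted p of 0.0463. The numbers do not pair the libraries by the rule fixed beforehand, so the fit without a block stayed the main one. Only the pair numbered 5 fell short of that rule (correlation 0.052), while pairs 1, 3 and 4 were at 0.43, 0.43 and 0.75. The labels leave open what a number stands for. If the numbers do stand for pairs, the fit without a block, the permutation tests and the splits of the libraries leave that pairing out. DESeq2 called 65 genes higher and 17 lower, and limma-voom 0. All 82 DESeq2 genes were among those edgeR tested, and in 70 of them the groups did not overlap, which calling them from the same values favours. DESeq2 led with Marco (adjusted p = 2.51e-09), Mmp14 (1.98e-07) and Ly6i (7.32e-06). Leaving out control 5 and malonyl-CoA 4, a choice made after seeing the data, left 0 genes past the threshold in edgeR.

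No enzyme that makes or uses malonyl-CoA passed the gene test. Acaca, which makes malonyl-CoA from acetyl-CoA (ENSMUSG00000020532, chromosome 11, 84129672 to 84401651), averaged 54.9 ± 16.8 CPM in control and 74.8 ± 19.3 with malonyl-CoA (SD, n = 4 each; log2 fold change 0.45, SE 0.23, edgeR adjusted p = 0.516). Fasn, the fatty acid synthase, averaged 261 ± 113 and 404 ± 115 CPM (log2 fold change 0.63, SE 0.30, edgeR adjusted p = 0.515). Without control 4 the log2 fold change was 0.68 for Acaca and 0.96 for Fasn, and without malonyl-CoA 4 that of Acaca was 0.25. Mlycd, the decarboxylase that removes malonyl-CoA, had a log2 fold change of 0.20 (SE 0.17), and Cpt1a, the transferase that malonyl-CoA inhibits, of 0.07 (SE 0.13). Both of these change sign when GC content and length are corrected for, to -0.064 and -0.039, and Cpt1a also without malonyl-CoA 4, to -0.022. Mlycd was at 0.33 without control 4 and 0.063 without control 5, and Cpt1a at 0.0094 without control 1, 0.14 without control 4 and 0.13 without malonyl-CoA 5. Of the 10 tested members of the list of malonyl-CoA enzymes, 7 were higher and 3 lower (camera adjusted p = 0.708).

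Other lists of lipid metabolism likewise did not pass. In fatty acid synthesis and desaturation 16 of 23 members were higher, with a median log2 fold change of 0.15 (camera adjusted p = 0.336). Acly, which makes cytosolic acetyl-CoA, had a log2 fold change of 0.30 (SE 0.12) and the elongase gene Elovl5 one of -0.28 (SE 0.12). In cholesterol synthesis and uptake 17 of 25 were higher (median 0.08, camera adjusted p = 0.0726), among them the sterol regulator gene Srebf2 (0.35, SE 0.13), which was at -0.0064 after the GC and length correction. The cholesterol list passed without control 1 (camera adjusted p = 0.0141), control 3 (0.00335) or malonyl-CoA 4 (3.87e-05), with library size only (0.0453) and with no low-count filter (0.0398). Without malonyl-CoA 4 so did fatty acid synthesis (0.0397) and triglyceride metabolism (0.0123). Without both libraries numbered 4, none of the cholesterol, fatty acid synthesis and triglyceride lists passed. Control 4 scored -0.34 for cholesterol, -0.077 for fatty acid synthesis and -0.30 for triglyceride genes, against -0.31, -0.072 and -0.26 in malonyl-CoA 4. Leaving out malonyl-CoA 4 alone therefore keeps a control with similar scores. In fatty acid oxidation 20 of 29 were lower (median -0.04, camera adjusted p = 0.0656), with Hadhb at -0.39 (SE 0.13) and Echs1 at -0.31 (SE 0.11). This list passed without control 5 (camera adjusted p = 0.0188), malonyl-CoA 1 (0.0450) or malonyl-CoA 5 (0.0495). Triglyceride synthesis, storage and lipolysis had 17 of 23 higher (camera adjusted p = 0.265), and targets of the sterol sensor LXR 10 of 12 (camera adjusted p = 0.284), with Nr1h3, the LXR gene itself, at 0.70 (SE 0.21). The LXR score of all 4 malonyl-CoA libraries lay above every control (exact permutation p = 0.0286, adjusted p = 0.396). PPAR targets had 10 of 18 higher (camera adjusted p = 0.871), where the median of 0.03 was positive and the test pointed down. Genes of coenzyme A synthesis and breakdown had 13 of 18 lower (camera adjusted p = 0.265), with a median of -0.11 and a mean of 0.0018. Without control 5 and malonyl-CoA 4 the lists of coenzyme A (camera adjusted p = 0.0197), fatty acid synthesis (0.0137), triglyceride metabolism (0.0447) and cholesterol synthesis (4.77e-05) passed. Adjusted over each list alone, 0 members of these 7 lists passed.

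Inflammatory and interferon-responsive genes stood together above the other genes. All 28 tested members of the NF-kB list were higher with malonyl-CoA, with a median log2 fold change of 0.76, and so were all 32 of the interferon list, with a median of 0.60. In the NF-kB list Nfkb2, a subunit of the factor, averaged 29.2 ± 7.18 CPM in control and 55.5 ± 6.00 with malonyl-CoA (SD, n = 4 each), the adhesion receptor gene Icam1 had a log2 fold change of 0.91 (SE 0.24) and the chemokine gene Ccl5 one of 1.28 (SE 0.34). In the interferon list Oas2, which senses double-stranded RNA, averaged 2.73 ± 0.95 and 7.67 ± 3.05 CPM (SD, n = 4 each), with Zbp1 at 0.97 (SE 0.25) and Isg20 at 0.85 (SE 0.22). Over all genes 0 members passed edgeR's test, and 9 in each list passed when adjusted over the list alone. Camera with a preset correlation gave an adjusted p of 8.76e-15 for NF-kB and 1.04e-14 for interferon. The correlation estimated from the data was 0.72 for NF-kB and 0.53 for interferon, and with it camera's adjusted p was 0.532 for both lists. The score of 3 malonyl-CoA libraries lay above every control in both lists and that of malonyl-CoA 4 did not (exact permutation p = 0.143 for NF-kB and 0.0571 for interferon, each with an adjusted p of 0.396). Without control 4 the NF-kB median was 0.53 and camera's adjusted p 2.05e-06.

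**Figure D3:**
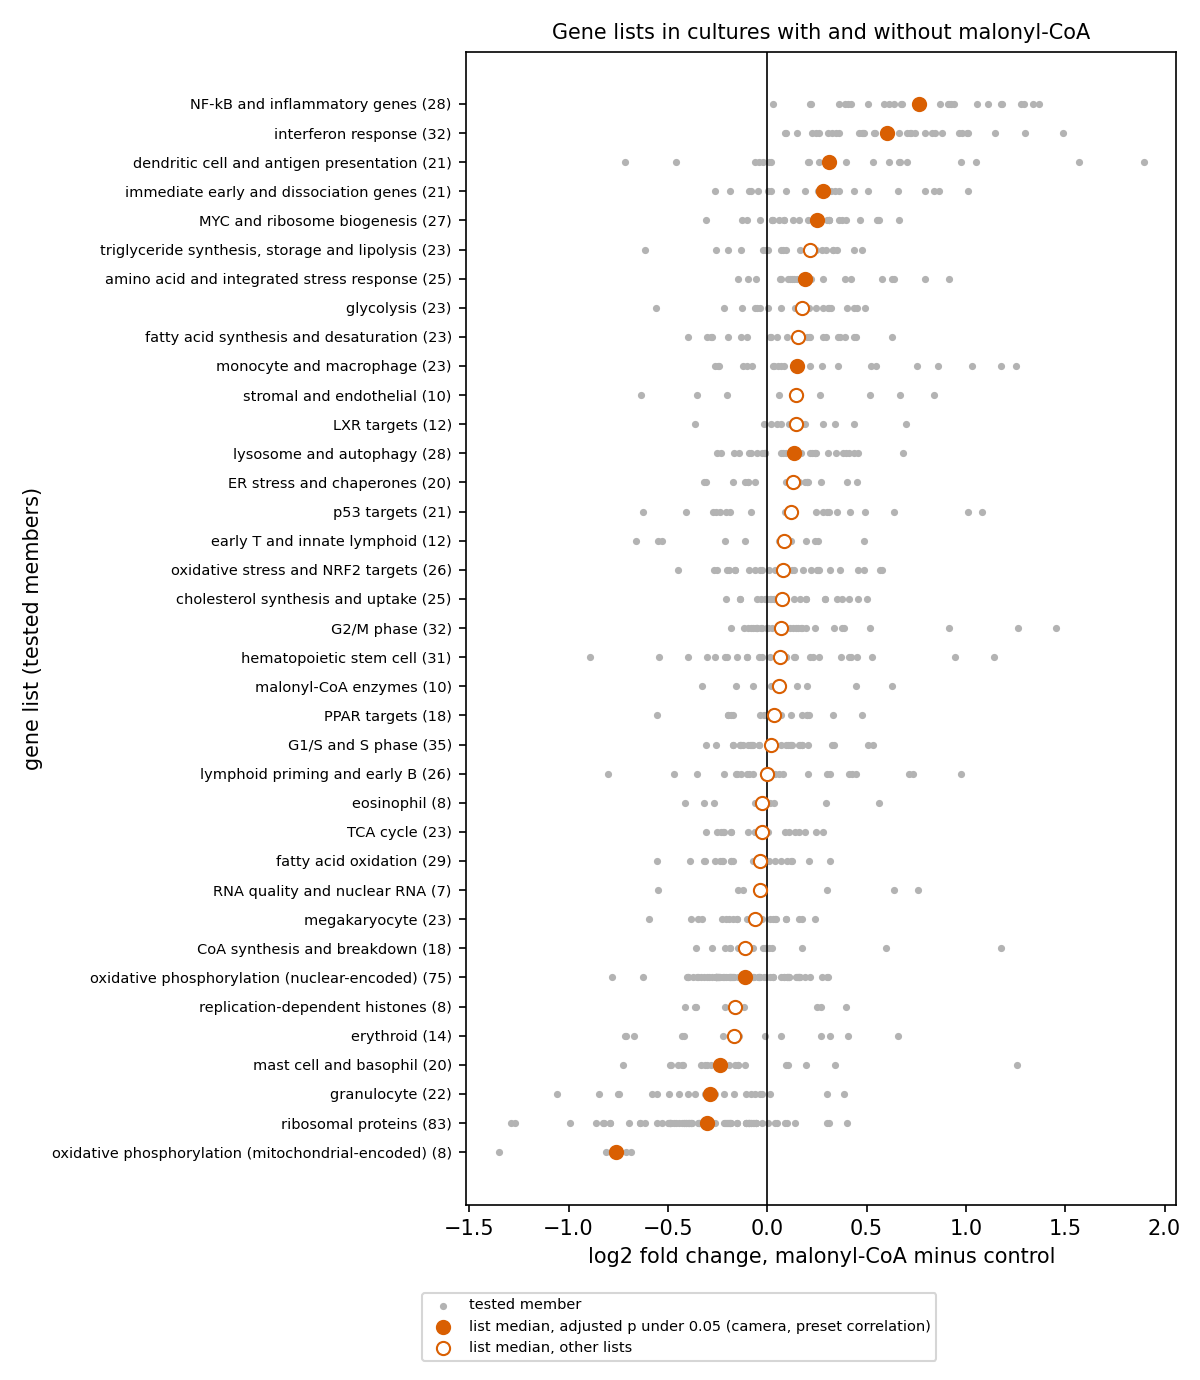
Each row is a gene list fixed before the data were examined, with the number of tested members, grey points for the log2 fold change (malonyl-CoA minus control) of each member and a circle for the list's median, filled where camera with the preset correlation gave an adjusted p under 0.05. The highest medians are those of NF-kB (0.76) and interferon genes (0.60), and the lowest that of mitochondrial-encoded genes (-0.76).

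Integrated stress response, immediate early and lysosome lists were also higher, by camera with the preset correlation. In the amino acid and integrated stress response 22 of 25 members were higher (median 0.19, camera adjusted p = 0.000742, and 0.532 as the adjusted p with an estimated correlation). Cebpb, a transcription factor of myeloid and stress programmes, averaged 18.1 ± 6.83 and 34.3 ± 2.62 CPM (SD, n = 4 each), and Ppp1r15a, which ends the response, had a log2 fold change of 0.64 (SE 0.16). These 2 were the members that passed adjusted over the list alone. Immediate early and dissociation genes had 16 of 21 higher (median 0.28, camera adjusted p = 0.00714, and 0.613 as the adjusted p with an estimated correlation), among them Junb (1.01, SE 0.29) and Jun (0.84, SE 0.24). That call was lost without control 4 (adjusted p = 0.243), without malonyl-CoA 5 (0.0723) and after the GC correction (0.273) or the GC and length correction (0.107). Lysosome and autophagy genes had 17 of 28 higher (median 0.13, camera adjusted p = 0.0271, and 0.759 as the adjusted p with an estimated correlation), and 3 passed adjusted over the list alone: the cathepsin genes Ctsz (0.69, SE 0.15) and Ctsa (0.38, SE 0.10) and the regulator Tfe3 (0.46, SE 0.12). The lysosome call was lost without any 1 of 5 libraries (controls 4 and 5, malonyl-CoA 1, 3 and 5), with an adjusted p of 0.124 to 0.242, and after the GC correction (0.1498) or the GC and length correction (0.177).

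Myeloid markers moved in different directions. Monocyte and macrophage genes had 17 of 23 members higher (median 0.15, camera adjusted p = 0.0130, and 0.613 as the adjusted p with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, averaged 219 ± 16.4 and 315 ± 27.8 CPM (SD, n = 4 each), and the Fc receptor gene Fcgr1 had a log2 fold change of 1.25 (SE 0.34), and these 2 passed adjusted over the list alone. Dendritic cell and antigen presentation genes had 16 of 21 higher (median 0.31, camera adjusted p = 0.00387, and 0.629 as the adjusted p with an estimated correlation), with Fscn1 at 1.90 (SE 0.49) and Ciita, the master regulator of MHC class II, at 1.05 (SE 0.34). Both calls were lost without control 4 (adjusted p = 0.289 for monocyte and 0.210 for dendritic cell genes) and without malonyl-CoA 3 (0.0673 for both), and the monocyte call also without malonyl-CoA 1 (0.0897) and with a 1 CPM filter (0.0672). Granulocyte genes had 19 of 22 lower (median -0.29, camera adjusted p = 2.18e-05, and 0.532 as the adjusted p with an estimated correlation). Chil3 averaged 146 ± 23.8 and 97.5 ± 13.9 CPM (SD, n = 4 each), and Ms4a3 and the alarmin gene S100a8 had log2 fold changes of -0.44 (SE 0.15) and -1.06 (SE 0.39), the latter -0.62 without control 5. The granulocyte score of all 4 malonyl-CoA libraries lay below every control (exact permutation p = 0.0286, adjusted p = 0.396). Mast cell and basophil genes had 15 of 20 lower (median -0.24, camera adjusted p = 0.000117, and 0.532 as the adjusted p with an estimated correlation), and Hpgd (-0.73, SE 0.19) and the monoamine transporter gene Slc18a2 (-0.45, SE 0.12) passed adjusted over the list alone. Bulk RNA gives marker levels, not cell numbers.

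**Figure D4:**
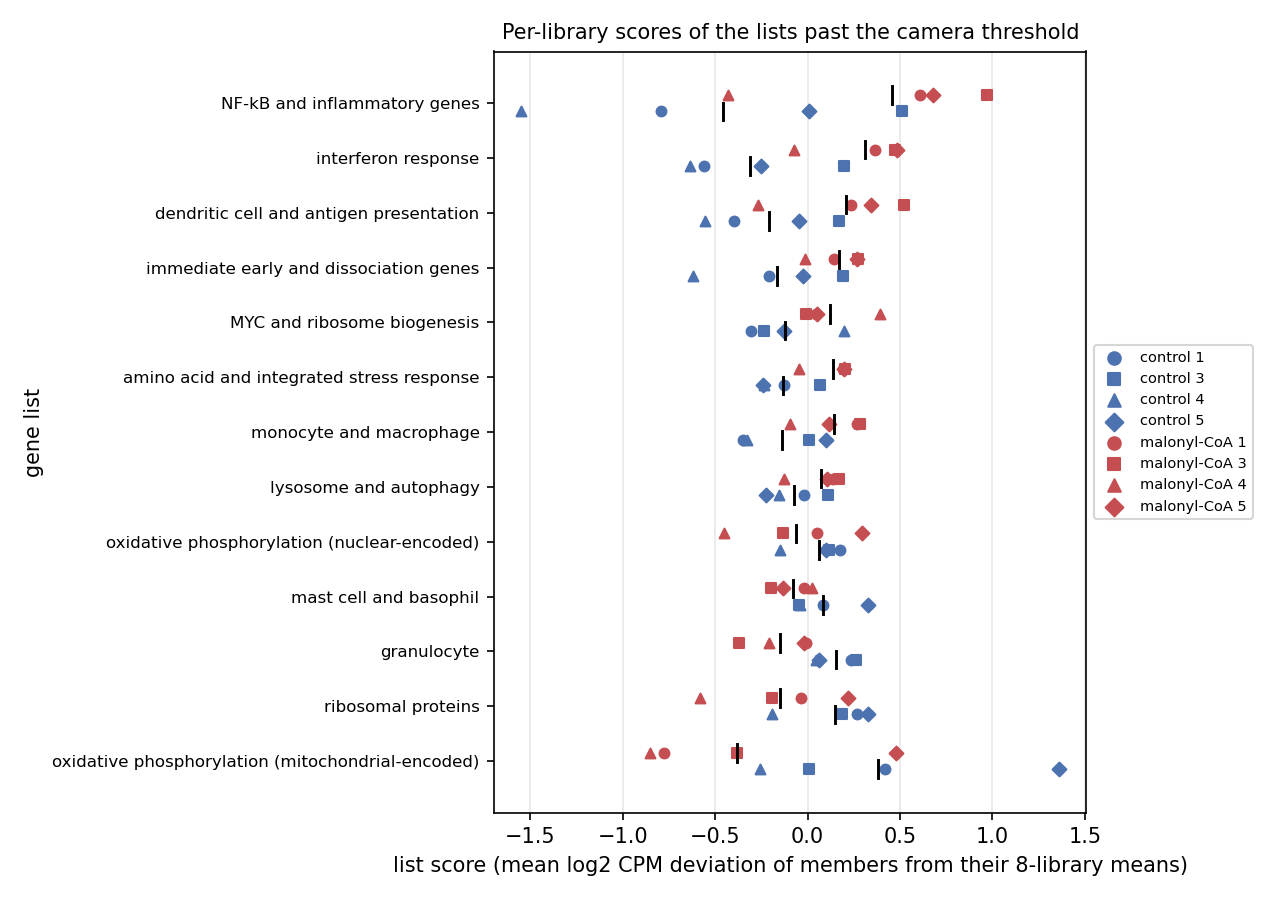
Points give the score of each library, the mean log2 CPM deviation of a list's members from their 8-library means, for the 13 lists past the camera threshold, with controls in blue, malonyl-CoA libraries in red, symbols for the replicate number and black bars for the group means. The granulocyte scores of the groups do not overlap, and in NF-kB and interferon genes malonyl-CoA 4 lies below control 3, and in NF-kB genes also below control 5.

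Stem cell and lymphoid lists, named in the purpose of the study as stem and progenitor behaviour and lymphoid reconstitution, did not differ as groups. Stem cell genes had 19 of 31 members higher (camera adjusted p = 0.918), with a positive median of 0.07 where camera pointed down. Adjusted over the list alone 3 members passed, all lower with malonyl-CoA: Cd34, at 598 ± 41.4 and 454 ± 20.1 CPM (SD, n = 4 each), the transcription factor gene Hlf (log2 fold change -0.55, SE 0.15) and Sult1a1 (-0.89, SE 0.22). Lymphoid priming and early B genes had 13 of 26 higher (median -0.0013, camera adjusted p = 0.955). Rag2, a subunit of the recombinase that assembles antigen receptor genes, averaged 8.03 ± 1.27 and 4.60 ± 0.57 CPM (SD, n = 4 each) and passed adjusted over the list alone. Its partner Rag1 had a log2 fold change of -0.47 (SE 0.19), the terminal transferase gene Dntt -0.35 (SE 0.12) and the cytokine receptor gene Il2rg 0.71 (SE 0.20). Early T and innate lymphoid genes had 7 of 12 higher (median 0.09, camera adjusted p = 0.527, test pointing down). Erythroid genes had 9 of 14 lower (median -0.16, camera adjusted p = 0.0552), with Car1 at -0.72 (SE 0.19), and this list passed without control 1 (adjusted p = 0.0316) or malonyl-CoA 1 (0.0266) with library size only (0.0453), with no low-count filter (0.00192) and after the GC correction (0.00569) or the GC and length correction (0.0309). Megakaryocyte genes had 14 of 23 lower (camera adjusted p = 0.115), passing without control 1 (0.00771) or malonyl-CoA 3 (0.0373) and after the GC correction (0.0293). Eosinophil genes had 4 of 8 lower (camera adjusted p = 0.779), and the shared cytokine receptor gene Csf2rb (0.57, SE 0.15) passed adjusted over that list alone. Stromal and endothelial genes had 7 of 10 higher (camera adjusted p = 0.284).

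Genes of the ribosome and of mitochondrial respiration were lower as groups. Of 83 tested genes with ribosomal protein symbols 74 were lower, with a median log2 fold change of -0.31 (camera adjusted p = 8.50e-11, and 0.613 as the adjusted p with an estimated correlation). The 83 include 3 annotated pseudogenes (Rps3a2, Rps3a3 and Rps4l, looked up after their values were seen), and without them 72 of 80 were lower, with a median of -0.30. Without malonyl-CoA 4 the median of the 83 was -0.19. Rpl13 averaged 114 ± 31.6 and 66.1 ± 18.2 CPM (SD, n = 4 each). Many ribosomal protein genes have near-identical pseudogene copies, and the counter's class of reads with several positions held 38.2% to 51.1% of tallied reads, so levels of single members are uncertain. Of 13 mitochondrial-encoded respiratory genes in the files, 8 passed the count filter and were tested. All 8 were lower (median -0.76, camera adjusted p = 9.37e-05, and 0.613 as the adjusted p with an estimated correlation). Whether reads with several positions lowered the counts of the others was not tested. The gene mt-Co1 averaged 18634 ± 8057 and 10816 ± 6025 CPM (SD, n = 4 each; log2 fold change -0.78, and -0.48 without control 5 or -1.25 without malonyl-CoA 5). The mitochondrial-encoded median was -0.40 without control 5 (camera adjusted p = 0.00758) and -1.19 without malonyl-CoA 5. Without control 5 and malonyl-CoA 4 the ribosomal protein median was -0.11, and the mitochondrial-encoded median was -0.20 with the call lost (adjusted p = 0.0860). Nuclear-encoded respiratory genes had 53 of 75 lower (median -0.11, camera adjusted p = 0.00387, and 0.785 as the adjusted p with an estimated correlation). The test of that list turned direction without malonyl-CoA 4 (adjusted p = 0.987) and was lost after the GC and length correction (0.566). Genes of MYC-driven ribosome biogenesis had 23 of 27 higher (median 0.25, camera adjusted p = 0.00860, and 0.629 as the adjusted p with an estimated correlation), with Bop1 at 0.46 (SE 0.22, and 0.26 without control 5), and were lost without control 3 (0.0904) or malonyl-CoA 4 (0.0932). Over all genes and over each of these 4 lists alone, 0 members passed. Glycolysis genes had 17 of 23 higher (camera adjusted p = 0.0552), with Hk1 at 0.49 (SE 0.21, and 0.33 without malonyl-CoA 4), and passed without control 1 (0.0116), control 3 (0.000739) or malonyl-CoA 4 (0.000161), with library size only (0.0368) and with no low-count filter (0.0223). Genes of the TCA cycle had 15 of 23 lower (camera adjusted p = 0.336), passing without both libraries numbered 5 (0.0276) and turning direction without malonyl-CoA 4 (0.987).

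Cell cycle, damage and quality lists did not pass. Genes of G1/S and S phase had 20 of 35 higher (camera adjusted p = 0.955) and those of G2/M 21 of 32 (camera adjusted p = 0.431), where Mki67 averaged 64.0 ± 47.8 and 176 ± 241 CPM (SD, n = 4 each). Without malonyl-CoA 4 the direction of the G2/M list turned (camera adjusted p = 0.864) and the log2 fold change of Mki67 was -0.21. Targets of p53 had 13 of 21 higher (camera adjusted p = 0.664), and Perp, a desmosomal p53 effector, was lower (-0.62, SE 0.15) and passed adjusted over the list alone. Genes of ER stress had 13 of 20 higher (camera adjusted p = 0.336), those of oxidative stress 15 of 26 (camera adjusted p = 0.524) and replication-dependent histones 3 of 8 (camera adjusted p = 0.386). Nuclear and quality-linked RNAs had 4 of 7 lower (camera adjusted p = 0.664), where the median of -0.04 and the mean of 0.12 differ in sign. Malat1 and Neat1, long RNAs kept in the nucleus, had log2 fold changes of 0.64 (SE 0.58) and 0.76 (SE 0.57), which became -0.36 and -0.33 without malonyl-CoA 4. Without that library the p53, oxidative stress and nuclear RNA lists passed camera (adjusted p = 0.0300, 0.00897 and 0.0119). Without both libraries numbered 4, the nuclear RNA list passed camera (adjusted p = 0.0360) and the p53 and oxidative stress lists did not. Of all 37 lists, 13 passed camera with the preset correlation, 8 higher and 5 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.532.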

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

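Of the tests in this part, the splits of the libraries by gene count, list count and GC trend and the trend without control 5 were set before their results were seen, and those on ribosomal protein and mitochondrial-encoded genes after, as was the requirement that a value lie 2 standard errors beyond its bound. That error was first taken over genes, and one over libraries was added last, because members of a list move together. The error over libraries is a jackknife of the distance between a value and its bound, and is given as SE below. These 2 errors differed in 5 of 11 tests here and in the last part, and an explanation counts as argued against only where both put it there. For the 4 tests of the GC and length correction, which uses the same libraries before and after, a jackknife of the share of the median kept was added after that and stands in place of the error over libraries. It changed 1 verdict, that on NF-kB genes.

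Malonyl-CoA 4 lay far from the other 3 malonyl-CoA libraries in most of the measures where a library stood alone. Of 406 groups of 4 libraries tested for a value far from the rest, 31 held one, where about 20 are expected because chance gives about 1 in 20 groups. Its share of reads in no gene, a class that enters no comparison, was 2.94% against 1.19% to 1.34% in its group and at most 1.56% in the controls. Its list scores, in log2 units around the 8-library means, were low for cholesterol synthesis (-0.31), triglyceride metabolism (-0.26), PPAR targets (-0.25), the integrated stress response (-0.045) and oxidative stress (-0.28). They were high for G2/M (0.48), MYC and ribosome biogenesis (0.39) and nuclear RNA (0.83). Among named genes it was low in Fabp5 (80.4 CPM), Slc25a20 (24.2), Isg20 (12.3), Icam1 (38.6), Ly6e (1691), Fcgr1 (7.24), Cd9 (102) and Junb (51.5 CPM), and high in Pank4 (28.8), Chaf1a (119) and Neat1 (41.3 CPM). The rule compares a library with its own group only, and control 4 shared a part of this profile. Control 4 was the lowest control for cholesterol synthesis (-0.34), triglyceride metabolism (-0.30), PPAR targets (-0.32) and oxidative stress (-0.18). It was the highest for G2/M (0.17) and MYC (0.19). Control 5 was the most extreme control for the integrated stress response (-0.24) and nuclear RNA (0.33).

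Other libraries stood alone less often. Malonyl-CoA 1 had the highest rho of expression with GC share in its group (0.44), malonyl-CoA 3 the highest stem cell score (0.13), and malonyl-CoA 5 stood apart in Mlycd (26.1 CPM), Acly (593 CPM) and Sult1a1 (0.946 CPM). Control 5 was low in the LXR score (-0.20), Sesn2 (40.5 CPM) and Bop1 (37.1 CPM) and high in Ndufb4 (25.4 CPM). Control 3 was high in Bcl3 (12.96 CPM) and control 4 low in Rfc4 (76.4 CPM).

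The numbers of genes in DESeq2, of genes at an unadjusted p under 0.05 and of lists do not exclude chance in how the libraries fell into groups. In edgeR the real grouping gave 0 genes, so all 35 splits gave as many whatever their counts (highest other 5), and that count tests nothing. In DESeq2 the real grouping gave 82 genes, 4 of 35 splits gave as many, and the highest other, which exchanges control 4 and malonyl-CoA 5, gave 1374. That is many times the real count and points to a structure of the samples. Library composition, looked up after that count was seen, followed that split. In controls 1, 3 and 5 and malonyl-CoA 5 mitochondrial-encoded genes took 3.04% to 6.79% of gene counts, against 1.68% to 2.55% in the others. Ribosomal protein genes took 6.36% to 7.30% against 3.91% to 6.05%, and the first principal component separated the same libraries. What lies behind this difference was not tested. At an unadjusted p under 0.05 the real count was 1210, 8 splits reached it and the highest other was 3299. Camera called 13 lists, 16 splits called as many and the highest other was 20.

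Ribosomal protein and mitochondrial-encoded genes were lower with malonyl-CoA, with medians of -0.31 and -0.76. None of 3 technical explanations is argued against, since each value lay within 2 standard errors over libraries of its bound (-0.15 and -0.38), and the shares kept by the GC and length correction, 0.80 (SE 0.26) and 0.49 (SE 0.15), of theirs (0.5). Given with the SE of their distance to the bound, the medians were -0.19 (SE 0.09) and -0.62 (SE 0.35) without malonyl-CoA 4. Without control 5 they were -0.26 (SE 0.14) and -0.40 (SE 0.26). After the GC and length correction they were -0.25 (SE 0.05) and -0.38 (SE 0.10). These libraries or the trend and the treatment therefore cannot be told apart. By the error over genes alone, control 5 and the trend would be argued against for ribosomal protein genes and malonyl-CoA 4 for mitochondrial-encoded genes. In both lists control 4 scored with malonyl-CoA 1, 3 and 4, and malonyl-CoA 5 with controls 1, 3 and 5, as in the split with the most DESeq2 genes. Ribosomal protein scores were 0.19 to 0.33 in controls 1, 3 and 5 and malonyl-CoA 5, and -0.58 to -0.033 in the rest. Mitochondrial-encoded scores were 0.010 to 1.36 and -0.86 to -0.26. Library composition and treatment therefore cannot be told apart here. An effect of malonyl-CoA on these transcripts stays open and was not tested.

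Log2 fold changes followed the GC share of transcripts, with a Spearman's rho of 0.44 across genes, which are not independent replicates. Chance cannot be excluded, since 5 of 35 splits gave a rho as large in size and the highest other was 0.53. Without control 5 the rho was 0.24 against a bound of 0.22 (SE of the distance 0.03), so that library may account for a part of the trend. Its part and that of the treatment cannot be told apart with 4 libraries a group. The treatment is an open explanation that was not tested.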

How the results depend on the processing

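The GC and length corrections, the comparison without control 5 and malonyl-CoA 4 and the permutation of list scores were chosen after seeing the data. EdgeR's count of 0 genes higher and 0 lower held in all single leave-outs, with RLE factors or library size only, with a 1 CPM filter, in limma-voom and in the legacy fit. At an unadjusted p under 0.05 edgeR gave 1210 genes. Without a low-count filter 1 gene was higher (Marco, edgeR adjusted p = 0.0228), and DESeq2 called 65 higher and 17 lower. The cause of these differences was not tested. The 13 lists past camera became 0 with an estimated correlation, 0 in fry's directional test and 0 in the exact permutation of list scores. Fry's mixed test, which ignores direction, passed 2 lists, mast cell and basophil and erythroid (adjusted p = 0.0486 each). The permutation could hardly pass a list, since 22 of the 37 would have to reach its smallest p of 0.0286. These tests allow for correlation between members or compare libraries rather than genes. Depth limits genes near 1 CPM most.

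With the replicate number as a block edgeR called 144 genes higher and 28 lower, of which 42 were among the 82 of DESeq2, and the smallest adjusted p was 0.0463. With the block and the GC and length correction it called 14 higher and 3 lower, the latter Rpl13, Tsc22d1 and Cd63, named here because they were so few, after their values were seen. The numbers do not pair the libraries by the rule fixed beforehand, because same-numbered libraries correlated at 0.05 to 0.75 and each had to exceed 0.1. As a hint from the data, not the design, 6 of 8 libraries correlated best with their own number. With the block the lysosome list did not pass camera (adjusted p = 0.0932) and glycolysis did (0.0129). With the block and the GC correction megakaryocyte (0.00824) and erythroid genes (0.0125) passed, and with the block and the GC and length correction megakaryocyte and G2/M genes (0.0236 each). The lysosome list did not pass in these settings either (0.239 and 0.201), nor did nuclear-encoded respiratory genes in the latter (0.233). The sign of the lymphoid list turned with the block (camera adjusted p = 0.794), and also with the block and the GC correction (0.601) or the GC and length correction (0.830). With the block and the GC correction the malonyl-CoA enzymes turned (0.949) and Mlycd was at -0.036. With the block and the GC and length correction the malonyl-CoA enzymes (0.287) and the TCA cycle (0.830) turned, and Mlycd was at -0.072, Cpt1a at -0.037, Srebf2 at -0.018 and Neat1 at -0.012.

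In 21 results the sign turned in at least 1 setting, and the cause was not tested. Only nuclear-encoded respiratory genes were past the threshold in either of the settings compared. With the GC correction camera's adjusted p was 0.649 for malonyl-CoA enzymes, 0.903 for the lymphoid list and 0.927 for nuclear RNA, and Mlycd was at -0.032. With the GC and length correction it was 0.291 for malonyl-CoA enzymes and 0.739 for the TCA cycle, and the log2 fold changes were -0.064 for Mlycd, -0.039 for Cpt1a and -0.0064 for Srebf2. Without control 5 and malonyl-CoA 4 it was 0.729 for malonyl-CoA enzymes, 0.908 for PPAR targets and for G1/S, 0.780 for nuclear-encoded respiratory genes, 0.5002 for stem cell, 0.364 for lymphoid and 0.747 for early T genes. In that setting Cpt1a was at -0.024, Pank4 at -0.019, Mki67 at -0.17, Neat1 at -0.18, Lars2 at -0.015 and Malat1 at -0.22. The lymphoid list also turned with library size only (0.969) and the stem cell list without a low-count filter (0.836). In fry the adjusted p was 0.872 for PPAR targets, 0.843 for stem cell and 0.756 for lymphoid genes, and in the exact permutation of scores 0.746, 0.620 and 0.396.

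Over the leave-outs, where signs turned, camera's adjusted p ranged from 0.259 to 0.987 for malonyl-CoA enzymes, 0.636 to 0.989 for PPAR targets, 0.0276 to 0.987 for the TCA cycle and 1.69e-08 to 0.987 for nuclear-encoded respiratory genes. It ranged from 0.0300 to 0.995 for p53 targets, 0.351 to 0.989 for G1/S, 0.223 to 0.969 for G2/M, 0.390 to 0.995 for stem cell and 0.536 to 0.995 for lymphoid genes. For eosinophil genes it was 0.322 to 0.996, for oxidative stress 0.00897 to 0.995 and for nuclear RNA 0.0119 to 0.984. Log2 fold changes ranged from -0.022 to 0.14 for Cpt1a, -0.21 to 2.05 for Mki67, -0.33 to 1.10 for Neat1 and -0.36 to 1.02 for Malat1. Over all alternatives, 46 list results newly passed and 68 no longer did, not counting those whose direction turned. Named genes numbered 157, of which 57 turned sign or moved by over 1.5 times in log2 fold change without at least 1 library, 24 passed with the block and 21 in DESeq2.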

Other observations

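All tests in this part were chosen after the higher NF-kB and interferon medians had been seen, and the standard errors over libraries given here were added after those over genes, and those of the shares kept after both. The SE beside a median or a bound is that of the distance between them, and the SE beside a share is that of the share.

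NF-kB and interferon genes were higher with malonyl-CoA, with medians of 0.76 and 0.60. A GC and length trend is argued against as the whole cause: after correction the medians were 0.73 and 0.64 (camera adjusted p = 1.68e-18 and 4.10e-24), and the shares kept, 0.96 (SE 0.09) and 1.07 (SE 0.11), lay over 2 standard errors above 0.5, though by its distance to a bound of 0.38 (SE 0.21 over libraries) the NF-kB median alone would leave the trend open. A single library stays open: camera passed without each library in turn (largest adjusted p = 2.05e-06 for NF-kB and 1.75e-06 for interferon), but the lowest medians, 0.53 (SE 0.16) without control 4 and 0.49 (SE 0.22) without control 1, lay within 2 standard errors of bounds of 0.38 and 0.30, for interferon by the error over libraries alone. Chance cannot be excluded, since 5 of 35 splits gave an NF-kB score difference as large as the real 0.91 (highest other 1.38), and more RNA of monocytes and macrophages could also contribute and cannot be told apart: the NF-kB score less the monocyte score differed by 0.63 between groups (exact permutation p = 0.229, n = 4 each). A response to malonyl-CoA itself, or to anything else in the preparation added with it, stays open and was not tested, because both were present in the same libraries.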
